A study of Mus musculus with 157 samples.

How the data were processed

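Liver RNA of 157 male pre-Collaborative Cross mice was measured on Affymetrix whole-transcript arrays, 1 array per mouse and 1 mouse per strain, per the labels. These strains were partly inbred at the time of sampling and descend from 8 founder strains, per the series design text. The labels' protocols place each mouse in a programme of alcohol exposure and exercise before it was killed; they do not say which mouse received what, so no treatment comparison was made.

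Probes were summarised per Ensembl gene with a custom chip definition built on NCBI 37 and Ensembl 49, per the series design text. RMA and the affy package are named, per the submitters' processing notes, and their versions are not given in the sources used here. The deposited values are a score per gene and array. Testing the values showed that all 23176 genes, within a tolerance of 6e-05, equal the standard normal quantile of the array's rank for that gene divided by the highest rank plus 1, with tied arrays at their mean rank. No label describes this step. A deposited score therefore orders the 157 mice for 1 gene, with a lowest possible value near -2.49 and a highest near 2.49, and carries no expression level, fold change or spread. Differences below are in score units, where 1 unit is about 1 SD of a gene over the mice.

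The design had been written for log2 values. With rank scores, the planned account of expression spread among strains and the search for genes with separate clusters of mice had no meaning and were left out. The planned filter, which asked for 8 arrays above the median of the table, kept all 23176 genes. No reference table used here paired the Ensembl identifiers with symbols or coordinates, so no gene was given a symbol. The 33 gene lists fixed beforehand, the check of sex-linked genes and the test of neighbouring genes were therefore not used here. The rule for named genes, fixed before the data were examined, took the genes with the smallest adjusted p of each test (for the trend, 5 in each direction). As no identifier was paired with a symbol, this was narrowed afterwards, and only the 2 rising and 2 falling identifiers with the smallest adjusted p for the trend over kill day are printed.

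Mice were grouped by the kill date in the labels. Dates at most 3 days apart formed 1 cohort, which gave 10 kill cohorts of 5 to 37 mice from 18 kill dates. Array labels gave 8 hybridization batches of 11 to 24 arrays on 4 hybridization days, 4 fluidic stations and 4 slots. The series design text speaks of 6 batches, and the batch numbers of the labels were used. Strain numbers were put into blocks of 1000 (blocks 0 to 5, the number divided by 1000 and rounded down). The labels do not state what a block means.

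Linear models were fitted to the scores with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend). Kill cohort was tested by an F test with hybridization batch as a covariate, and the linear trend over days after the first kill day by limma's moderated statistic with the same covariate. Kill day within cohort, fluidic station and slot were tested with batch and cohort as covariates, and batch with cohort as a covariate. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all 23176 genes. For each test, labels were permuted 100 times within batch (within cohort for kill days and for batch). Because mice of a cohort share their kill days, whole cohorts were also reassigned to kill days 100 times for the trend and 100000 times for components 1 to 5. The mean share of a gene's variance added by the label was compared with that of the permuted labels. Because each strain gave 1 mouse, p-values rest on the spread among these mice, in which strain, environment and array error are mixed. For the identifiers printed below, moderation replaced the gene's own spread by a value shared by the genes. Their errors and p-values therefore hold no spread of the single gene. Without trend, the SE of the slope was 0.0896 for each of these identifiers, and with trend it was 0.0898 for each. A kill cohort F test without moderation called 770 genes, against 568 with it. The number of arrays limits the precision, and replicate numbers only name arrays.

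Principal components, correlations between arrays and correlations between genes were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Shares of components by label used 100000 permutations of the label (larger shares counted), correlations 100000 two-sided permutations, and pairs of arrays 10000 one-sided permutations. The limma steps were tested on simulated data of 23176 genes with 100 changed genes per size. The simulated genes varied independently apart from a batch effect. For the kill cohort F test, genes were changed in cohort 7 alone, the largest cohort (37 mice). There, 48 of 100 genes changed by 1 SD and 99 of 100 changed by 1.5 SD were recovered, with 2 false calls. Changes in smaller cohorts or in correlated genes were not simulated. For the linear trend, with the change spread over the full range of kill days, 58 and 96 of 100 were recovered, all in the right direction, with 13 false calls.

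Alternatives fixed before the data were examined covered the scaling of arrays, the batch term, the strain-number block, the grouping of kill dates, the moderation and a rank test. Alternatives chosen after seeing the data were the removal of 2 arrays with unusually wide scores, strain number as a linear covariate, early and late cohorts apart, an unmoderated F test, for some tests limma without trend, centred arrays for the components, and batch and cohort means removed for gene pairs. No array fell under the fixed limit on correlation with the other arrays (0 arrays).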

Results

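Liver transcript scores were compared among 157 male mice of the pre-Collaborative Cross, a set of partly inbred strains bred from 8 founders (129S1/SvImJ, A/J, C57BL/6J, CAST/Ei, NOD/LtJ, NZO/H1LtJ, PWK/Ph and WSB/Ei). Each strain gave 1 mouse, and the founders were not analysed here. The mice were killed in 10 successive cohorts, with 20, 21, 11, 5, 6, 10, 37, 22, 12 and 13 mice in cohorts 1 to 10. Scores for 23176 Ensembl genes rank the mice for each gene and hold no expression level, so all differences are in score units. The files do not pair the Ensembl identifiers with gene symbols, and genes are therefore described as sets and by identifier.

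Liver scores differed between kill cohorts for 568 of 23176 genes (limma F test, adjusted p under 0.05, n = 157 mice). Of these genes, 186 had a positive and 382 a negative slope over kill day, whether or not that slope passed a test; 356 of the 568 also passed the trend test. The 382 genes with a negative slope had a mean batch-adjusted score of 0.545 ± 0.274 (SD over genes) in cohort 1 and -0.424 ± 0.296 in cohort 8. The 186 genes with a positive slope had -0.314 ± 0.298 in cohort 1 and 0.452 ± 0.347 in cohort 8. The sets were chosen on the same mice, so these means describe the called genes and are not a further test. Cohort 8 had the highest mean for 84 of the genes with a positive slope and the lowest for 182 of those with a negative slope. In the latest cohorts the separation was smaller: genes with a positive slope stood at -0.0090 in cohort 9 and 0.204 in cohort 10, and those with a negative slope at -0.137 and -0.201.

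Kill cohort accounted for 7.26% of a gene's variance on average, against 5.57% ± 0.263 (SD of 100 permutations) for labels permuted within batch, and none of the 100 permutations reached the observed share. The number of called genes fell to 206 without cohort 1, to 299 without cohort 7 and to 258 without cohort 8. The strain-number block changed along with the cohorts, and with this block as a covariate limma called 0 genes, with 2452 at an unadjusted p under 0.05.

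**Figure D1:**
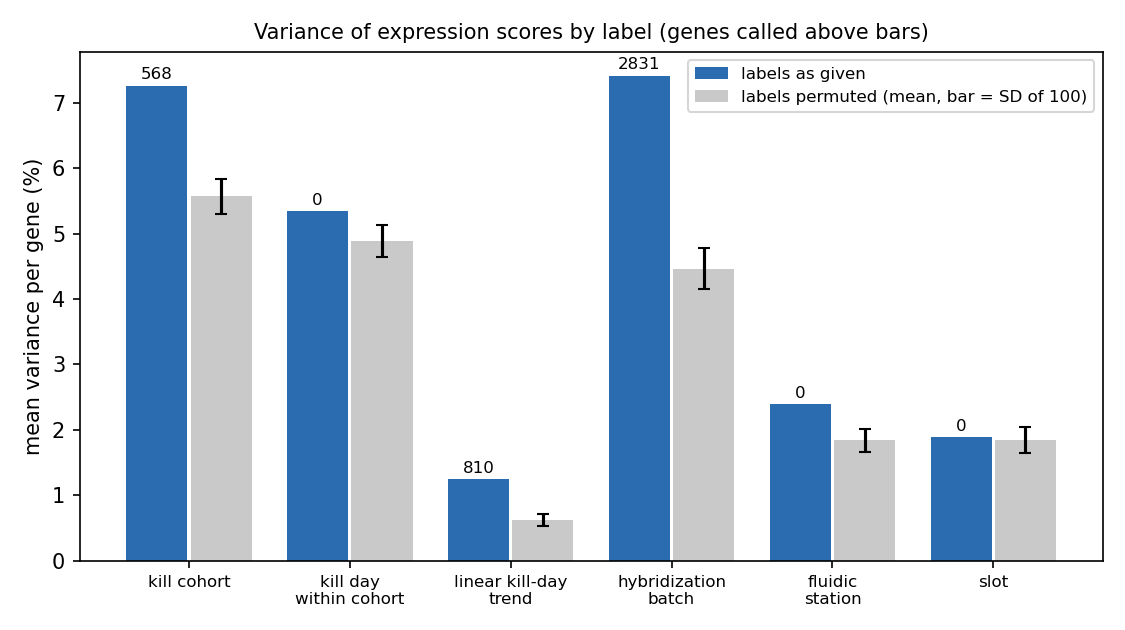
Mean percent of a gene's variance added by each label (blue bars) and by the same label permuted among single mice 100 times (grey bars, mean with SD), with the number of called genes above each blue bar. Kill cohort (7.26%), the linear kill-day trend (1.24%) and hybridization batch (7.41%) lie above all of their permuted values.

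The pairs of cohorts with the most called genes joined an early and a late cohort. Cohorts 1 and 7 differed in 810 genes, of which 231 were higher and 579 lower in cohort 7. Cohorts 1 and 8 differed in 655 genes (156 higher and 499 lower in cohort 8), and cohorts 2 and 8 in 348 (192 higher and 156 lower in cohort 8). Of the 24 pairs with 1 cohort among cohorts 1 to 6 and the other among 7 to 10, 11 had at least 1 called gene. Among the 15 pairs within cohorts 1 to 6, 3 pairs had any, with at most 36 genes, and among the 6 pairs within cohorts 7 to 10, 2 pairs had any, with at most 4. Differences were not limited to such pairs: cohorts 1 and 2 (20 and 21 mice) differed in 36 called genes. At an unadjusted p under 0.05 the counts were 3784 for cohorts 1 and 2, 4678 for cohorts 1 and 7 and 3527 for cohorts 1 and 8. No permuted counts were drawn for pairs of cohorts, so these unadjusted counts are no test. In the F test over all cohorts, 3885 genes lay under that p, and permuted labels gave a median of 918.5 and up to 2567. That test has 9 terms, so its permuted counts give no range for a single pair. Pairs differ in the number of mice, and small cohorts call fewer genes at the same difference.

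A linear trend over kill day was called for 810 genes, of which 263 rose and 547 fell (limma, adjusted p under 0.05, n = 157 mice). The trend added 1.24% of a gene's variance, against 0.616% ± 0.0944 for days permuted among single mice, with none of 100 permutations as large. Mice of a cohort share their kill days, and when whole cohorts were reassigned to kill days the share was 0.839% ± 0.174, with 2 of 100 orders as large. In all, 356 genes were called both for the trend and between cohorts; the trend is nearly a contrast of the cohort means that the cohort test compares, so this overlap is no separate evidence. Fitting the strain-number block left 0 genes called by limma. Taken apart, cohorts 1 to 6 and cohorts 7 to 10 also gave 0 each, with fewer mice and larger errors, which does not show that a trend was absent there.

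ENSMUSG00000024052 rose by 0.505 ± 0.0898 score units per 100 days (SE, limma, adjusted p = 8.76e-05). Its lowest and highest cohort means were -0.911 ± 0.916 (SD, n = 11) in cohort 3 and 0.630 ± 0.912 (SD, n = 22) in cohort 8. Such means are given here for each identifier and are not adjusted for batch, unlike the slopes. ENSMUSG00000021500 rose by 0.497 ± 0.0898 per 100 days (limma adjusted p = 0.000104), from -0.676 ± 0.834 (SD, n = 21) in cohort 2 to 0.831 ± 0.666 (SD, n = 13) in cohort 10. ENSMUSG00000065402 fell by 0.587 ± 0.0898 per 100 days (limma adjusted p = 1.50e-06), from 0.721 ± 0.430 (SD, n = 11) in cohort 3 to -0.715 ± 0.698 (SD, n = 13) in cohort 10. ENSMUSG00000026816 fell by 0.550 ± 0.0898 per 100 days (limma adjusted p = 1.09e-05), from 1.21 ± 0.720 (SD, n = 20) in cohort 1 to -0.568 ± 0.581 (SD, n = 12) in cohort 9. These errors and p-values treat the mice as independent, although mice of a cohort share their kill days. Whole cohorts were not reassigned for single genes. With the strain-number block as a covariate, the slopes of ENSMUSG00000024052, ENSMUSG00000021500, ENSMUSG00000065402 and ENSMUSG00000026816 were 0.365, 0.362, -0.537 and -0.547, each with an SE of 0.147 in place of 0.0898, at limma adjusted p of 0.752, 0.761, 0.681 and 0.660. In cohorts 1 to 6 alone the slopes, in the same order, were 0.433 ± 0.237, 0.454 ± 0.240, -0.420 ± 0.228 and -0.925 ± 0.236 (SE), and in cohorts 7 to 10 alone -0.0564 ± 0.237, 0.431 ± 0.241, -0.113 ± 0.227 and -0.159 ± 0.237; none passed in either set, and ENSMUSG00000024052 changed sign in the later one by less than its error.

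Mice killed on neighbouring days of 1 cohort did not differ in any called gene. The limma test of kill day within cohort called 0 genes, with 1713 at an unadjusted p under 0.05 (median of permuted days 968) and a smallest adjusted p of 0.518. Kill days added 5.34% of variance against 4.88% ± 0.242 for permuted days, and 5 of 100 permutations were as large. Over whole arrays, mice of the same cohort killed on the same day had a mean correlation of 0.0167, against 0.0033 for mice of the same cohort killed on different days. That difference of 0.0133 passed a one-sided permutation test within cohorts (p = 0.005, adjusted p = 0.005 over 4 comparisons). Cohorts 5, 9 and 10 had 1 kill date each and enter only the same-day mean. The size of the difference therefore also holds differences between cohorts, which the permutation within cohorts keeps in place. This permutation did not hold hybridization batch, and within some cohorts the kill days were unevenly spread over the batches. Arrays of the same batch had a mean correlation 0.0317 above that of other pairs. The same-day difference may therefore carry part of a batch difference, and it was not tested with batch held.

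Strain-number block and kill day were largely aligned. Of the 76 mice with strain numbers in blocks 0, 1, 2 and 4, 70 were killed in cohorts 1 to 6 and 6 in cohorts 7 to 10. Of the 81 mice with strain numbers in blocks 3 and 5, 3 were killed in cohorts 1 to 6 and 78 in cohorts 7 to 10. Fitted after batch, the strain-number block called 151 genes in limma and added 4.11% of variance, against 3.08% ± 0.210 for permuted labels. Fitted after batch and kill cohort, it called 0 genes and added 3.34%, against 2.89% ± 0.136 for permuted labels.

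**Figure D2:**
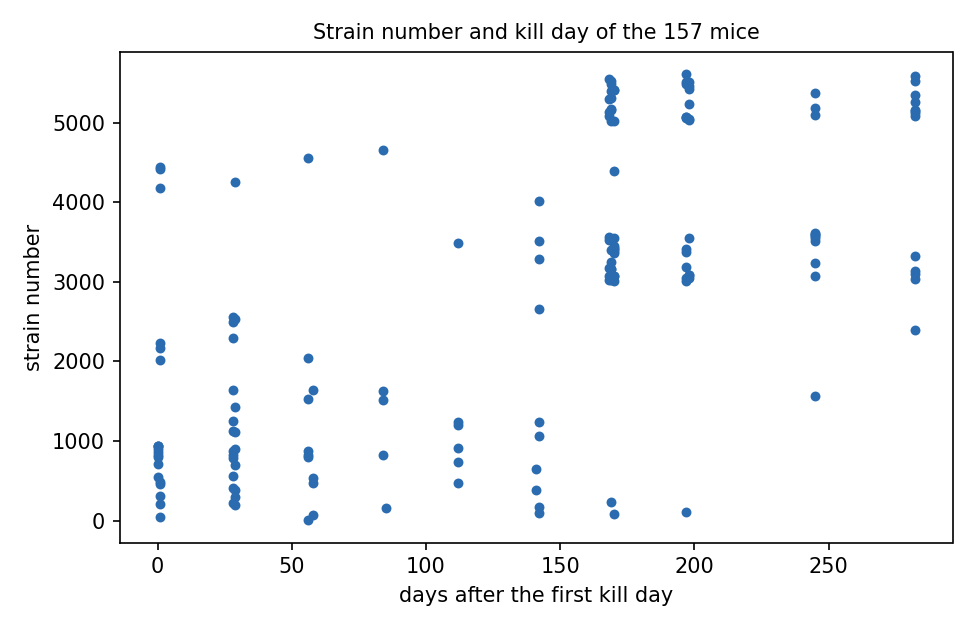
Strain number of each of the 157 mice (points) against its kill day, in days after the first kill day. Most of the 84 mice of cohorts 7 to 10 have strain numbers in blocks 3 and 5, which hold 3 of the 73 mice of cohorts 1 to 6.

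Hybridization batch was tested as a technical label named by the submitters. Scores differed between the 8 batches for 2831 genes (limma F test with cohort as a covariate), with 7.41% of variance against 4.46% ± 0.318 for permuted batches and none of 100 permutations as large. Batch 3 differed from the mean of the other batches in 1460 genes, 1050 of them higher and 410 lower. Batch 4 differed in 417 genes (104 higher and 313 lower) and batch 5 in 171 (86 higher and 85 lower), while batches 2 and 6 differed in 0 by limma. With the 4 hybridization days in place of the batches, 999 genes were called.

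Fluidic station and slot gave no called gene. For station, limma called 0 genes, with 2634 at an unadjusted p under 0.05 (median of permuted labels 1035) and a smallest adjusted p of 0.152. Station added 2.39% of variance against 1.84% ± 0.176, and 1 of 100 permutations was as large. For slot, limma called 0 genes, with 1175 at an unadjusted p under 0.05 and a smallest adjusted p of 0.862; it added 1.88% of variance against 1.84% ± 0.198, and 28 of 100 permutations were as large.

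The main axes of variation among the livers followed the cohorts only in part. Component 1 held 12.1% of the variance, component 2 3.31%, component 3 2.93%, component 4 2.43% and component 5 1.87%. In all, 25 components exceeded those of 20 tables with each gene permuted and together held 42.8% of the variance. Kill cohort accounted for 33.5% of component 4 (permutation test, adjusted p = 5e-05 over 10 tests) and also passed the test on component 5 (13.8%, adjusted p = 0.0141) and component 3 (11.4%, adjusted p = 0.0419). It accounted for 5.72% of component 1 (adjusted p = 0.498) and 2.03% of component 2 (adjusted p = 0.961). Batch passed the test on all 5 components, with 24.5% of component 2 (adjusted p = 5e-05), 20.0% of component 5 (adjusted p = 7e-05), 17.7% of component 4 (adjusted p = 0.00027), 11.8% of component 1 (adjusted p = 0.0141) and 11.4% of component 3 (adjusted p = 0.0151). The smallest p these permutations can give is 1e-05 before adjustment.

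Component 4 correlated with kill day over the 157 mice (Pearson r = 0.485, Spearman rho = 0.464; permutation of single mice, p = 1e-05 for both, the smallest possible, adjusted p = 0.0001 over 10 relations). With whole cohorts reassigned to kill days, the permutation p was 0.0091 for r and 0.0106 for rho (adjusted p = 0.0457 and 0.0528 over 5 components), so r passed and rho did not. Without the 2 mice farthest from the median day r was 0.478. Within the 8 batches r ranged from 0.0648 to 0.682 and was positive in 8 of 8. Within cohorts 1 to 6 (73 mice) r was 0.243 and within cohorts 7 to 10 (84 mice) it was -0.0923; each set spans a narrower range of days. Component 4 also rose with strain number (r = 0.326, rho = 0.280, adjusted permutation p = 0.00035 and 0.00175; r = 0.324 without the 2 mice farthest from the median number, and -0.0591 to 0.687 within batches). The relation of component 5 to kill day (r = -0.211, rho = -0.215; r = -0.194 without the 2 farthest mice, and -0.660 to 0.0727 within batches) passed with single mice permuted (adjusted p = 0.0197 and 0.0171) and did not with whole cohorts reassigned (p = 0.122 and 0.128, adjusted p = 0.305 and 0.312). Component 5 fell with strain number (r = -0.272, rho = -0.262, adjusted permutation p = 0.0018 and 0.0032; r = -0.269 without the 2 farthest mice, and -0.571 to -0.0529 within batches). The other 6 relations did not pass with single mice permuted.

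**Figure D3:**
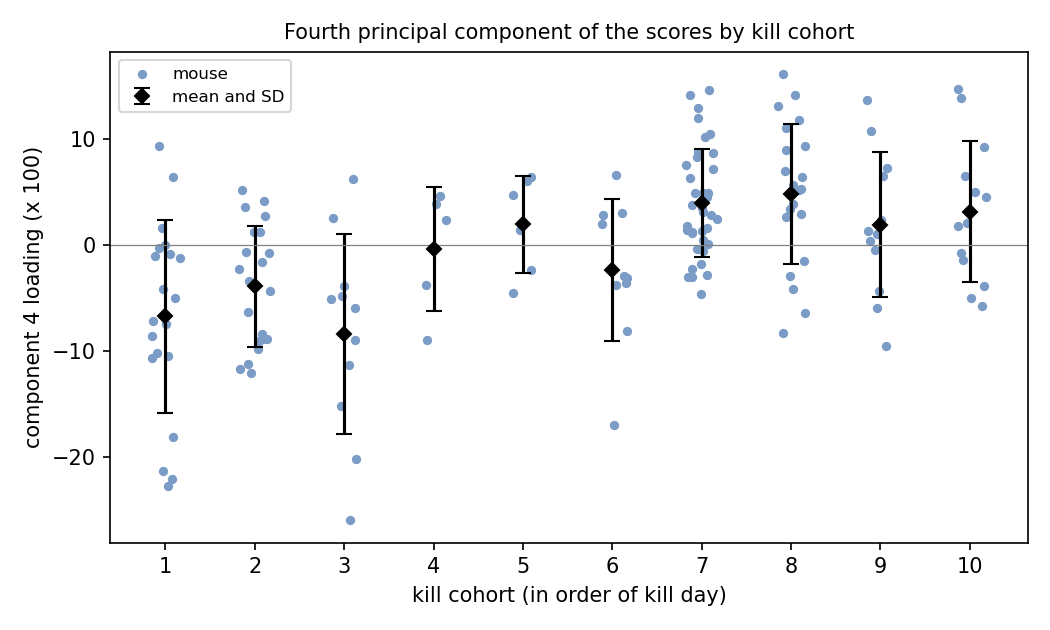
Loading of each mouse on component 4, times 100 (points), by kill cohort in order of kill day, with the mean and SD of each cohort (black). Means lie between -8.39 and 1.99 in cohorts 1 to 6 and between 1.95 and 4.87 in cohorts 7 to 10.

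Arrays of different mice correlated little. The median correlation between 2 arrays over all genes was -0.0072, with 5th and 95th percentiles of -0.172 and 0.163 among 12246 pairs. Arrays of the same batch had a mean correlation of 0.0214, against -0.0103 for other pairs (adjusted p = 0.0002, one-sided permutation test). Arrays of the same kill cohort had 0.0097 against -0.0086 (adjusted p = 0.0002), and arrays with the same strain-number block 0.0037 against -0.0092 (adjusted p = 0.0004). Kill cohort and strain-number block were each permuted within batch, without holding the other. As these labels were largely aligned, either difference may carry part of the other.

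Many gene pairs varied together over the mice. Of 268551900 gene pairs, 514936 (0.192%) had a correlation of at least 0.5 in size, 51068 of them negative, and 3912 reached 0.7. At least 1 partner at 0.7 was found for 1071 genes (4.62%). With each gene permuted over the arrays no pair reached 0.5. After batch and cohort means were removed, 394904 pairs reached 0.5 and 932 genes (4.02%) had a partner at 0.7. These correlations are over mice; genes that share probe sequence can correlate for that reason, which was not examined.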

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

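Removal of the 2 wide arrays, the linear strain-number covariate, early and late cohorts apart, the unmoderated F test and limma without trend for batch, kill days, stations and slots, centring for components and removal of batch and cohort means for gene pairs were chosen after seeing the data. For the counts and components, 49 alternatives stayed within 1.5 times of the reported value; those that did not are given here.

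The 568 genes differing between kill cohorts became 0 with the strain-number block as a covariate, 76 with strain number as a linear covariate, 0 in cohorts 1 to 6 and 2 in cohorts 7 to 10. They became 206 without cohort 1, 299 without cohort 7, 258 without cohort 8 and 891 by a Kruskal-Wallis test on batch-adjusted scores. Without each replicate of cohort 4 in turn they ranged from 553 to 592. The 810 genes with a trend became 0 with the strain-number block, 17 with the linear strain number (0 rising and 17 falling), 0 in cohorts 1 to 6 and 0 in cohorts 7 to 10. The 2831 genes differing between batches became 999 with hybridization days in their place. Subsets of cohorts hold fewer mice and a narrower range of days; otherwise the cause was not tested.

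For kill days, stations and slots, all alternatives run (quantile normalization, limma without trend and the removal of the 2 wide arrays) gave 0. The 4 named genes kept their direction in 10 alternatives except for ENSMUSG00000024052 in cohorts 7 to 10 (slope -0.0564 ± 0.237, SE); all 4 were called in 6 of them, 2 with the linear strain number and 0 with strain-number block or in either set of cohorts. With strain-number block fitted, the slope of ENSMUSG00000026816 was -0.547 ± 0.147 (SE), against -0.550 ± 0.0898 without it: the slope was close and the error larger. The other slopes became smaller in size, with the same larger error. ENSMUSG00000024052 went from 0.505 to 0.365, ENSMUSG00000021500 from 0.497 to 0.362 and ENSMUSG00000065402 from -0.587 to -0.537.

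Not run were the alternatives for expression spread, clusters of mice, gene lists and neighbouring genes, which need levels or symbols, and those without low-correlation arrays, of which there were 0. The low-value filters are void on rank scores. No paired analysis was possible because replicate numbers only follow the order of the samples and pair no mice.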

Other observations

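The counts over regroupings were planned, and the outcome each explanation would give was written down after they were seen. The test of cohort order was chosen after the trend was seen, and its outcomes were written down before it was run; for the kill cohorts, the fits with strain-number block, without the batch term and with centred arrays were planned and their reading was written down afterwards. Chosen only after the results were seen were the variance shares of cohort and strain-number block after each other, the 2-set and linear codings of strain number, the use of the wide arrays, of centring and of batch as explanations of component 1, and the tests of ties. A gap test of single arrays was run 33 times on sets of 4 to 10 mice and found none that stood apart from its set. Among the kill cohorts only 4, 5 and 6 are of that size. The larger cohorts were therefore not checked as a whole by this test, among them cohorts 2 and 9, which hold the 2 arrays of widest scores.

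Among 101 groupings of single mice (100 drawn and the real one), 1 called as many genes as the real kill cohorts (568 genes, highest other 0). For the real batches it was also 1 (2831, highest other 1), and in each case this was the real grouping. These counts argue against chance for both, but 1 of 101 is the smallest share that 100 draws can give. Permuted slot labels called up to 824 genes, so a random labelling can at times call many genes. For the trend, 1 of 101 groupings of single mice called as many as the real 810 (highest other 9), but these groupings break the cohorts apart and so test any difference between cohorts. For the chance order of the kill cohorts, whole cohorts were reassigned to kill days: 3 of 101 orders, the real one included, called as many genes, and the highest other called 1071. This lay under the 0.05 level by a small margin, and with 100 orders drawn it does not firmly exclude chance order. At least 1 other order gave more called genes than the real one. For kill days within cohort, fluidic stations and slots the real count was 0, so 101 of 101 groupings had to call as many and the count decides nothing (highest other 1, 1 and 824; the source of the highest was not tested). Their shares of variance were reached by 5, 1 and 28 of 100 permutations.

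The first pattern was that scores differed between kill cohorts. Strain-number block as the whole cause is argued against, because kill cohort fitted after it still added 1.04 percentage points of variance over its permuted mean, with 0 of 100 permutations as large; in the other direction, strain-number block after kill cohort added 0.457 points, again with 0 of 100. Hybridization batch is argued against, because 538 genes were called without the batch term and 568 with it, and an array-wide shift by the 779 genes called after centring each array. Which of kill cohort and strain-number block the called genes follow cannot be told apart, since with both fitted 0 genes were called for either. Other codings of strain number left 6 genes for cohort (blocks joined into 2 sets) and 76 (a straight line over the number), so the 0 depends on the coding. Season, age, husbandry and the alcohol and exercise programme, which may have differed between cohorts, stay open and untested.

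The second pattern was the first component, on which an array of cohort 2 (replicate 2) and one of cohort 9 (replicate 9) lay farthest out; their scores had SDs of 1.40 and 1.57 (median of all arrays 0.943), with 1934 and 3760 genes at an extreme score, where 295.2 would be the average. These 2 arrays came from batches 2 and 6 and correlated at 0.667, the highest of 12246 pairs. They are argued against as the whole cause, because component 1 still held 10.4% of the variance without them; an array-wide shift is argued against by 11.7% after centring, and batch as the whole cause by the 11.8% of the component it accounts for. RNA quality and the cell makeup of the liver could also move many genes together and were not tested, and no biological explanation was tested.

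The third pattern was the number of tied scores within a gene. A gene had a median of 17 tied pairs of mice, from 7 to 29 between the 5th and 95th percentiles, with up to 110 for 1 gene and none for 9 genes. Rounding of the deposited scores is argued against as their source by the form of the scores. Unequal ranks of a gene lie at least 0.0158 apart in score, and the scores are given in steps of 0.0001. That gap is set by the rank form, so measuring it was no test. A common spread in rounding steps with a normal shape for all genes is also argued against. The variance of the number of tied pairs was 2.67 times its mean, against 1.06 times in a simulation of normal values in which every gene had the same spread in steps. Ties also depend on the shape of a gene's distribution, so a common spread with shapes that differ stays open. A candidate explanation, not tested directly, is that values were rounded before ranking, so that genes with few ties had the wider spread among mice; the values before ranking were not used here.

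Under that hypothesis, genes with few ties may hold more of the differences between mice and genes with many ties more of the array-related differences. In the 6603 genes with at most 13 tied pairs, kill cohort accounted for 7.73% of variance, against 7.11% in the 4853 genes with 23 or more. The difference of 0.62 points lay farther from the permuted mean of 0.0689 ± 0.171 than in any of 100 permutations. For hybridization batch the shares were 6.79% and 7.85%; the difference of -1.06 points also lay farther out than in any of 100 permutations (mean -0.0524 ± 0.145). Of the genes with fewest ties 3.89% were called between cohorts and 9.18% between batches, against 1.75% and 13.9% of those with most. The spread itself was not measured, and its link to ties stays a hypothesis.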
